A study of Rhizorhabdus wittichii RW1 with 18 samples.

How the data were processed

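The series compared total RNA of Rhizorhabdus (Sphingomonas) wittichii RW1, a bacterium that grows on dibenzofuran, on 18 one-colour (Cy3) Agilent arrays. The labels place the arrays in 6 groups of 3 replicates. Nothing in the labels used here says that the replicates of the 1 h group or of the saturated group came from separate cultures, so their p-values measure only the spread between these samples, which may be technical.

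Spot intensity values were deposited as Agilent Feature Extraction output, per the file headers from version 10.7.3.1 for 15 arrays and 10.5.1.1 for the 3 arrays of the saturated group, with background subtraction by that software and no normalization between arrays. The deposited series table holds values on a log2 scale for 5335 genes. How these were scaled and centred is not given in the sources used here. Set against the scanner values of the same array, after centring each gene on its median, the table's columns correlated across genes at r of 0.77 to 0.97 with slopes of 0.65 to 1.08. The medians of its columns in the order of replicates 1, 2 and 3 were -0.016, -0.016 and -0.017 for sand at 1 h, 0.011, -0.014 and 0.014 for liquid exponential, -0.042, -0.00064 and -0.032 for liquid stationary, -0.011, -0.018 and -0.015 for sand exponential, 0.0057, 0.0019 and 0.018 for sand stationary, and 0.027, 0.021 and 0.015 for the saturated group. The direction was therefore settled, while the exact scale and centring stayed unknown, and the table served only as an alternative.

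The main values were computed here as log2 of the processed signal minus the 75th percentile of that array's RW1 spots. Control spots were left out, as were 76 spots flagged as outliers over all arrays; 0 RW1 spots were saturated. The arrays carry 12873 spots for 5335 RW1 locus tags, with 3 spots for 3262 genes, 2 for 1014 and 1 for 1059. Spots of a gene were averaged. They differed by a median SD of 1.22 log2 units within an array, and their profiles over the arrays correlated at a median r of 0.48. Of the genes past the threshold with 2 or 3 spots, all spots moved the same way in 81.7% (16 h against 1 h in sand) to 98.9% (phases in liquid) over the comparisons of 2 groups. A gene was kept if at least 1 of its spots was well above background on all arrays of at least 1 group, which kept 5319 genes and left out 16. Gene values were missing in 13 cases where the only spot was an outlier. Between 86.6% and 99.8% of the RW1 spots of an array were well above background, and the median processed signal ran from 75.6 to 449. The number of arrays limits the precision.

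All 18 arrays were fitted in 1 model of 6 group means with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and 8 comparisons were taken from it, with statmod 1.5.0 for random blocks. A gene passed the threshold at a Benjamini-Hochberg adjusted p below 0.05 and a log2 change of at least 1, a 2-fold change. Adjusted p-values are limma's throughout. The SE and p-values rest on a variance per gene shared by all groups, so they do not describe the spread of the compared groups alone. The step was tested on simulated data for sand against liquid in exponential phase. Among 5327 simulated genes, of which 200 were changed, it recovered 89.6% of changes of 1.5 log2 units, 97.0% of changes of 2 and 100% of changes of 3, with 5 false calls. These figures describe the simulated data. The real replicates of exponential liquid were the least alike (r of 0.834 to 0.976), and no simulation of such unequal spread is reported here. Where a gene was not well above background on any array of its dimmer group, the fold is given as at least the mean of the brighter group over the mean of, per array, the higher of the lowest signal well above background and the gene's own.

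The files used here do not pair locus tags with gene names, and 0 of the 5335 tags matched the reference gene table provided, which is that of another strain. Tags are therefore printed as the files give them, at most 2 higher and 2 lower per comparison. Of the tags printed, Swit_1412, Swit_1349, Swit_4389, Swit_3903, Swit_5364, Swit_5365, Swit_4893, Swit_3723, Swit_3232, Swit_2267, Swit_3008, Swit_3189, Swit_5260 and Swit_3282 rest on 1 spot each. Their intervals and p-values measure the spread between arrays and do not cover the difference between spots. The names dxnA1, dxnA2 and dbfB for Swit_4897, Swit_4896 and Swit_4902 come from general knowledge of this strain and were not checked against a sequence. The rule fixed before the data were examined took, per comparison, the 10 largest changes each way past the threshold with every array of one group above every array of the other and a product that is not hypothetical, 3 members of each list called, and those 3 genes always. The clause on products could not be applied. Of 29 gene lists fixed in advance, 28 needed product names or replicons and were not run. The list of the dibenzofuran region, 42 consecutive tags with 34 measured, was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. No genome coordinates were used.

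The arrays lie on 4 slides. Slide 4 holds liquid exponential, sand exponential and replicate 3 of sand at 1 h, and slide 3 holds both stationary groups and the other 2 replicates at 1 h. The comparisons of sand with liquid at one phase thus lie within a slide, while a change of phase is also a change of slide, linked only through the 1 h group. The saturated group lies alone on slides 1 and 2 and was read with the older software. Its label names hot phenol for extraction but then repeats the text of the soil kit, so whether its extraction differed is unclear. No other group lies on those 2 slides, so the slide was not run there as a fixed block. A random block for the slide cannot remove a slide difference from that comparison either. Slide, software, and extraction if it differed, cannot be told apart from the condition.

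Replicate numbers were checked for pairing through the correlation across genes of the deviations from the group means. The numbers met the criterion, every pair over 0.1, for sand and liquid in stationary phase (r of 0.53, 0.65 and 0.46) and for the phases in liquid (0.33, 0.58 and 0.36). They did not for the other comparisons of a pair of groups. Stationary sand and exponential liquid, which differ in both environment and phase, also met it (0.16, 0.72 and 0.59). Meeting the criterion therefore does not show that the replicates were paired.

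Alternatives named before the data were examined were normexp background (offset 50), quantile normalization, median scaling, the deposited log2 table, no filter, the brightest spot, only the groups compared, a replicate block, the slide as a block, eBayes with trend and robust settings, no fold minimum, and each replicate left out. The normexp step used the median spot signal because the mean signal was not used here. Subtraction of each array's floor, the brighter genes alone, the slide as a random block and the arrays of 1 slide alone were added after seeing the data.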

Results

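Transcript levels of strain RW1 were measured in 6 groups of 3 arrays each, all with dibenzofuran as carbon source. Liquid cultures on dibenzofuran crystals (1.6 g per litre) were harvested in exponential phase at an optical density of 0.2 to 0.3, or in stationary phase at 0.9 to 1. Sand was coated by spraying 10 ml of a dibenzofuran solution of 100 mg per ml on 500 g. Cells were recovered from it 1 h after inoculation, after 16 h in exponential phase (16 microcosms pooled per replicate) and after 40 h in stationary phase (4 pooled). A last group grew exponentially in a saturated dibenzofuran solution. The design asked how this biodegrading bacterium responds in sand compared with laboratory culture, upon entry and during growth. Levels below are log2 signals relative to the 75th percentile of the array, as mean ± SD with n = 3.

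The genes of the initial dioxygenase, Swit_4897 (dxnA1) and Swit_4896 (dxnA2), which attacks dibenzofuran first, were lowest in stationary sand. Swit_4897 stood at 5.99 ± 0.96 in exponential liquid, 4.83 ± 0.55 in stationary liquid, 7.22 ± 0.14 after 1 h in sand, 4.53 ± 0.05 after 16 h and 2.39 ± 0.39 after 40 h. Swit_4896 stood at 0.76 ± 0.41 in the same 40 h group, against 5.28 ± 1.03 in exponential liquid. Swit_4902 (dbfB), for the dioxygenase that cleaves the ring of the first product, was lowest in stationary liquid at 2.32 ± 0.41 and stood at 3.60 ± 0.44 after 40 h in sand.

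**Figure D1:**
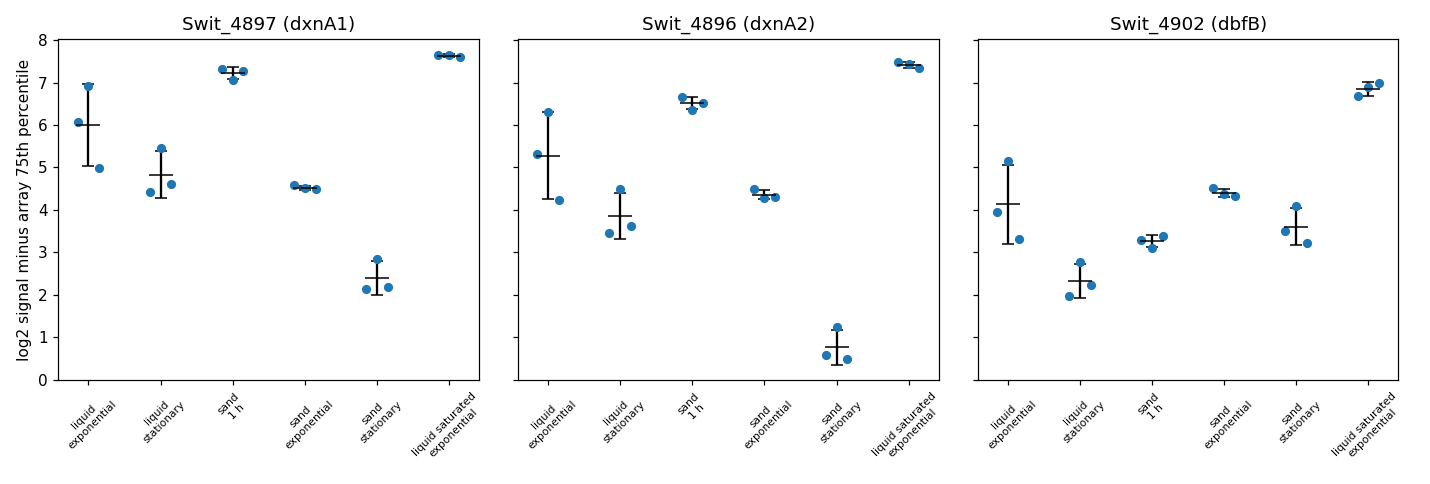
Log2 signal minus the 75th percentile of the array (vertical axis) of Swit_4897, Swit_4896 and Swit_4902 in the 6 groups; points are arrays, and bars are the mean and SD with n = 3. Swit_4896 lies at 0.76 in stationary sand and 3.85 in stationary liquid.

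The comparison of sand with liquid in exponential phase asked how growing cells differ between the environments. Swit_1412 was 28.3-fold higher in sand (95% interval 17 to 47, adjusted p = 3.44e-08) and Swit_1349 20.6-fold higher (adjusted p = 1.6e-07). Swit_1349 lies in an unbroken run of 21 consecutively numbered genes that all rose. Swit_4389 was 57.7-fold lower in sand (adjusted p = 1.89e-09) and Swit_0703 23.9-fold lower (adjusted p = 1.97e-07). Swit_4897 fell by 1.47 on the log2 scale (SE 0.36, adjusted p = 0.0025), while Swit_4896 changed by -0.92 and Swit_4902 by 0.26 without passing the threshold. The SE for Swit_4897 rests on a variance shared by all groups, while its SD was 0.96 in exponential liquid and 0.05 in exponential sand. It therefore does not describe the spread of these groups alone. The change of Swit_4897 was -1.01 without replicate 2 of exponential liquid and -1.97 without replicate 3, passing in both cases. Swit_4896 passed without replicate 3 of exponential liquid (-1.45, adjusted p = 0.00132) and with the brightest spot of the gene (-1.26), and stood at -0.41 without replicate 2. Swit_4902 stood at -0.15 without replicate 3 and at 0.77 without replicate 2, passing in neither case. In all, 1733 of 5319 genes passed, 429 higher and 1304 lower. This balance rested on the scaling: the median of all genes moved by 0.40 when arrays were scaled to their medians, which gave 785 higher and 662 lower, and quantile normalization gave 775 and 774. Of the main calls, 1091 were called in the same direction with median scaling. The normexp background gave 1046 genes. With the slide as a block 1719 genes passed, and within slide 4 alone 1691. As both groups lie wholly on slide 4, these fits cannot change the estimates, only their SE.

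In stationary phase, Swit_1152 was 41.2-fold higher in sand than in liquid (95% interval 30.3 to 56, adjusted p = 5.92e-11) and Swit_3903 40.1-fold higher, although only 1 of the 3 liquid arrays had Swit_3903 well above background. Its change of 5.32 log2 units was 4.37 without replicate 1 of stationary liquid and 6.03 without replicate 3. Swit_5364 was 52.8-fold lower in sand (adjusted p = 2.36e-07) and Swit_4893 18.4-fold lower (adjusted p = 7.11e-07). Swit_4893 belongs to the dibenzofuran list and to a run of 11 consecutive genes that fell, which also holds Swit_4897, 5.42-fold lower, and Swit_4896, 8.53-fold lower (adjusted p = 1.17e-05). Swit_4902 rose by 1.28 (SE 0.34, adjusted p = 0.00854), a call lost without replicate 2 of stationary sand (1.04, adjusted p = 0.0524). Of the 34 measured genes of the list, 19 fell, 3 rose and 12 did not pass, with the same 19 and 3 when adjusted over the list alone, and the median change was -1.29 (camera, adjusted p = 5.68e-08 over the 8 comparisons; adjusted p = 0.301 with an estimated correlation). Over all genes 867 passed, 416 higher and 451 lower, or 361 and 328 without replicate 2 of stationary sand. The normexp background gave 566. The slide as a block gave 853, and slide 3 alone 832, with the list median at -1.29 in both. As both groups lie wholly on slide 3, neither fit can change the estimates, so the unchanged median is no check.

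Between the phases, 350 genes were past the threshold in the same direction for sand against liquid, 99 higher and 251 lower, where independent lists would share 33.6 and 111. A further 32 genes passed in opposite directions. These comparisons share no arrays.

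**Figure D2:**
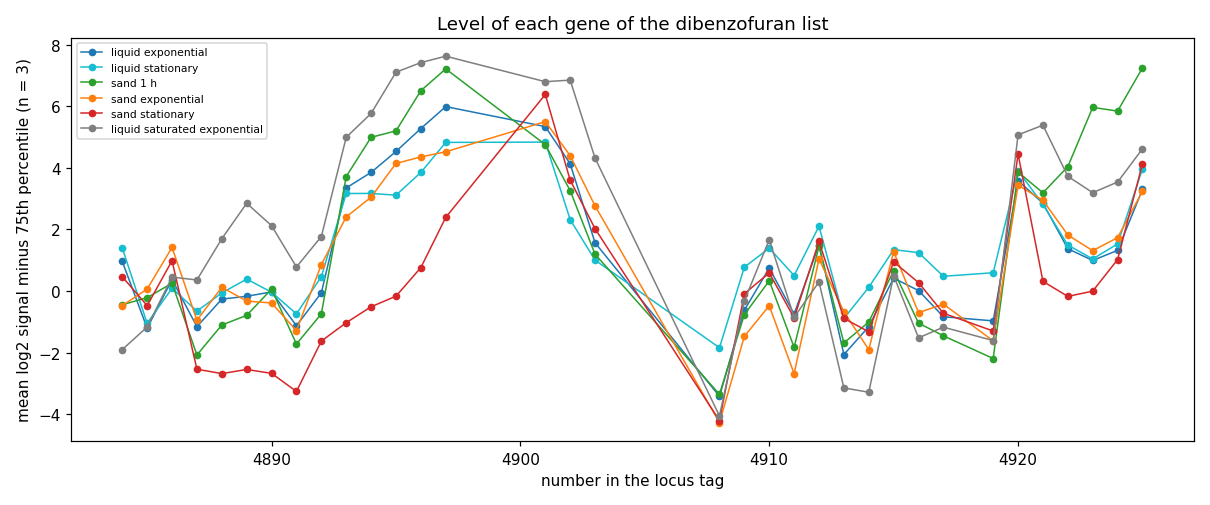
Mean log2 signal minus the 75th percentile (vertical axis, n = 3) of the 34 measured genes of the dibenzofuran list by the number in their locus tag (horizontal axis), with a line per group that also bridges tags not measured. In stationary sand Swit_4893 lies at -1.03, against 3.17 in stationary liquid.

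The change from exponential to stationary phase in liquid was taken as the laboratory reference. Swit_5364 rose 52.6-fold (adjusted p = 4.51e-06) and its neighbour Swit_5365 9.57-fold (adjusted p = 0.000144). Swit_3376 was 10.1-fold lower in stationary cells (adjusted p = 2.44e-05) and Swit_3723 9.29-fold lower (adjusted p = 0.00049). Leaving out 1 array moved Swit_5364 to 5.12 log2 units (without replicate 3 of exponential liquid, against 5.72) and Swit_3723 to -2.53 (without replicate 2). A block for the slide has a larger SE, and with it the calls of Swit_5365 (3.35 against 3.26 log2 units, adjusted p = 0.133), Swit_3376 (-3.03 against -3.34, 0.0863) and Swit_3723 (-2.91 against -3.21, 0.154) were lost while the changes stayed about as large. Swit_4902 fell by 1.81 (SE 0.34, adjusted p = 0.00204), Swit_4896 by 1.43 and Swit_4897 by 1.16 (adjusted p = 0.03). All 3 calls were lost with the slide as a block (-1.62, -1.41 and -1.09 in this order, adjusted p = 0.332, 0.427 and 0.53) and, with unchanged values, in the fit of these groups alone (adjusted p = 0.073, 0.155 and 0.202). The Swit_4897 call was also lost with median scaling (adjusted p = 0.0852), quantile normalization (-0.82, adjusted p = 0.178), the deposited table (-0.98) and without replicate 3 of stationary liquid. The Swit_4896 call was lost with quantile normalization (adjusted p = 0.0539). Both were lost without replicate 1 of stationary liquid and without replicate 1 of exponential liquid. Without replicate 2 of exponential liquid both were lost too (-0.70 for Swit_4897 and -0.92 for Swit_4896). Both held without its replicate 3 (-1.66 and -1.95). Of the dibenzofuran list, 8 genes rose and 4 fell, also when adjusted over the list alone. The 8 lie within Swit_4908 to Swit_4919. The 4 lie within Swit_4895 to Swit_4902 and include the 3 named genes. The list had a median change of 0.35 (camera, adjusted p = 2.68e-05; adjusted p = 0.392 with an estimated correlation), which does not describe the named genes. Without replicate 3 of exponential liquid this median was 0.0010 and did not pass, and without replicate 2 it was 0.64. Over all genes 361 passed, 222 higher and 139 lower. Median scaling gave 294 and 80, and quantile normalization 368 and 145. The balance rested on single arrays: it was 210 and 227 without replicate 2 of exponential liquid, 283 and 255 without replicate 3, and 223 and 216 without replicate 3 of stationary liquid. The phases lie on different slides. With the slide as a block 7 genes passed; its median SE rose from 0.237 to 0.434, and its estimates correlated with the main ones across genes at r = 0.87. No slide holds both groups. Without replicate 1 of stationary liquid 239 genes passed, the normexp background gave 136, and the fit of these groups alone gave 177.

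The same change of phase in sand raised Swit_3232 44.3-fold (adjusted p = 1.93e-10) and Swit_1152 26.5-fold (adjusted p = 1.61e-10). Swit_1412 fell 45-fold (adjusted p = 6.21e-09) and Swit_2267 39.8-fold (adjusted p = 4.06e-11). Swit_4896 was 12.1-fold lower and Swit_4897 4.38-fold lower in stationary sand, both within a run of 11 genes that fell. The Swit_4897 call was lost with the slide as a block (-2.06, adjusted p = 0.0567). Swit_4902 changed by -0.80, which did not pass, but it passed with quantile normalization (-1.13, adjusted p = 0.0287), median scaling (-1.01), the deposited table (-1.29) and without replicate 2 of stationary sand (-1.04). Of the dibenzofuran list, 14 genes fell and 4 rose, also when adjusted over the list alone, with a median of -0.63 (camera, adjusted p = 0.000891; adjusted p = 0.478 with an estimated correlation). Over all genes 1345 passed, 852 higher and 493 lower, against 599 and 674 with median scaling and 656 and 643 with quantile normalization. With the slide as a block 824 passed, and no slide holds both groups. The normexp background gave 843.

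The 2 phase changes shared 87 genes that rose and 16 that fell, where independent lists would share 35.6 and 12.9. A further 31 genes passed in opposite directions. Both changes of phase are also the same change of slide, which alone could create sharing, so independent lists are no full reference. With the slide as a block the shared genes numbered 4, against 103 in the main fit.

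Whether the change of phase differed between sand and liquid was tested directly as an interaction, in which the slide cancels. The change of Swit_3723 was 7.47 log2 units higher in sand (SE 0.69, adjusted p = 1.74e-06) and that of Swit_3722 6.49 higher (adjusted p = 2.09e-06), or 6.79 and 5.82 without replicate 2 of exponential liquid. For Swit_1412 the difference was -5.39 (adjusted p = 1.46e-06) and for Swit_3046 -5.07 (adjusted p = 1.43e-06). For Swit_4896, which fell in both, it was -2.17 (SE 0.53, adjusted p = 0.0051), while the differences of -0.97 for Swit_4897 and 1.02 for Swit_4902 did not pass. Swit_4897 passed with the deposited table (-1.71, adjusted p = 0.0169) and without replicate 2 of exponential liquid (-1.43), against -0.47 without replicate 3, where Swit_4902 passed (1.43, adjusted p = 0.0165). Of the dibenzofuran list, the change was lower in sand for 18 genes and higher for 1, also when adjusted over the list alone, with a median of -1.25 (camera, adjusted p = 5.87e-09; adjusted p = 0.301 with an estimated correlation). Over all genes 1343 passed, 926 higher and 417 lower, against 494 and 667 with median scaling and 635 and 674 with quantile normalization. The slide as a block gave 1284 and the normexp background 883.

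Entry into sand was examined 1 h after inoculation against exponential liquid cells. No group is labelled as the inoculum before it met the sand. The comparison therefore cannot separate a response to sand from the earlier state of the inoculum. Swit_3743 was 166-fold higher (95% interval 97.9 to 280, adjusted p = 1.94e-10) and Swit_5364 124-fold higher (adjusted p = 6.11e-09), the latter in a run of 8 genes that rose. Without replicate 3 of exponential liquid Swit_5364 changed by 6.35 log2 units, against 6.95. Swit_3008 was 24.7-fold lower (adjusted p = 8.93e-09), with 2 of the 3 sand arrays well above background, and Swit_2738 12.5-fold lower (adjusted p = 4.91e-08). Swit_4897 was 1.23 log2 units higher (adjusted p = 0.0121) and Swit_4896 1.23 (adjusted p = 0.0153). Both calls were lost with quantile normalization (0.41 and 0.50) and without replicate 3 of exponential liquid (0.73 and 0.71), and the deposited table gave -0.30 and -0.18. They were also lost with the slide as a block, at changes of about the same size (1.28 and 1.24, adjusted p = 0.113 and 0.139). The Swit_4896 call was lost, with an unchanged value, in the fit of these groups alone too (adjusted p = 0.0783). Swit_4902 changed by -0.87, which did not pass, but it passed with quantile normalization (-1.07, adjusted p = 0.0385), the deposited table (-1.35) and without replicate 3 of exponential liquid (-1.29). Of the dibenzofuran list, 7 genes rose and 4 fell, also when adjusted over the list alone, and the median was 0.0051 (limma's camera, adjusted p = 0.181). Without replicate 2 of exponential liquid it was 0.30, which passed with limma's camera at its preset correlation (p = 0.00362) and not at an estimated one (p = 0.32). Over all genes 1142 passed, 438 higher and 704 lower, against 690 and 294 with median scaling, 582 and 561 with quantile normalization, and 530 and 1065 without replicate 2 of exponential liquid. With the slide as a block 793 passed, and within slide 4, which holds 1 of the 1 h arrays and so no spread for that group, 590. The normexp background gave 585.

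Between 1 h and 16 h in sand, Swit_3008 rose 150-fold (adjusted p = 2.72e-11) and Swit_1412 49.2-fold (adjusted p = 1.37e-09). Swit_3743 fell 327-fold (adjusted p = 2.4e-11) and Swit_5364 313-fold (adjusted p = 3.51e-10), the latter within a run of 19 genes that fell. Swit_4897 fell by 2.69 and Swit_4896 fell by 2.15, the latter call being lost with the deposited table (-0.80, adjusted p = 0.12), while Swit_4902 rose by 1.14 (adjusted p = 0.0108), a call lost with the slide as a block (1.01, adjusted p = 0.152). Of the dibenzofuran list, 8 genes rose and 9 fell, also when adjusted over the list alone, with a median of -0.33 (limma's camera, adjusted p = 0.725). Over all genes 1573 passed, 635 higher and 938 lower, and quantile normalization gave 801 and 757. The slide as a block gave 1475, slide 4 alone 1270, where a single 1 h array takes its spread from the other groups, and the normexp background 1047.

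Of the genes higher at 1 h than in exponential liquid, 352 were lower again by 16 h, and of those lower at 1 h, 143 were higher by 16 h. Independent lists would share 77.2 and 84.0. The comparisons share the 1 h arrays, and 20 simulations of unchanged groups gave at most 0 shared genes. Such groups give about no calls, so this says nothing about the overlap that shared arrays create. Part of the excess may come from the shared arrays.

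Cells from the saturated solution were compared with those grown on crystals, both exponential and in liquid. Swit_4897 was 3.11-fold higher (adjusted p = 0.000637), Swit_4896 4.42-fold (adjusted p = 8.79e-05) and Swit_4902 6.58-fold higher (adjusted p = 3.39e-06) in the saturated solution. The first pair of calls was lost with the deposited table (0.67 and 1.05 log2 units). Swit_3008 was 26.7-fold higher (adjusted p = 8.63e-09) and Swit_3189 14.2-fold higher (adjusted p = 2.84e-10). Swit_5260 was at least 40.1-fold lower and Swit_3282 at least 21.8-fold lower, both not well above background on any saturated array. These bounds use the mean of exponential liquid and so depend on its single arrays, but no bounds without single arrays are reported here. The plain estimates, which take the dim saturated signals as they are and so go beyond the bounds, did move. Without replicate 2 and replicate 3 of exponential liquid, that of Swit_5260 was -8.00 and -6.79 log2 units, against -7.25. That of Swit_3282 was -6.91 and -5.96, against -6.35. Of the dibenzofuran list, 20 genes rose and 5 fell, also when adjusted over the list alone, with a median of 1.5 (camera, adjusted p = 1.43e-07; adjusted p = 0.301 with an estimated correlation). Over all genes 2614 of 5318 passed, 517 higher and 2097 lower, against 931 and 1397 with median scaling and 804 and 811 with quantile normalization. The deposited table gave 1170. The saturated arrays spanned 7.46 to 7.63 log2 units between their 5th and 95th percentiles, against 4.71 to 5.08 for the crystal cultures. With the slide as a random block 2623 genes passed. No other group lies on the slides of the saturated arrays, so that fit cannot remove a slide difference and is no check. Slide, software and scan, and perhaps extraction, differed together with the condition and cannot be told apart from it.

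**Figure D3:**
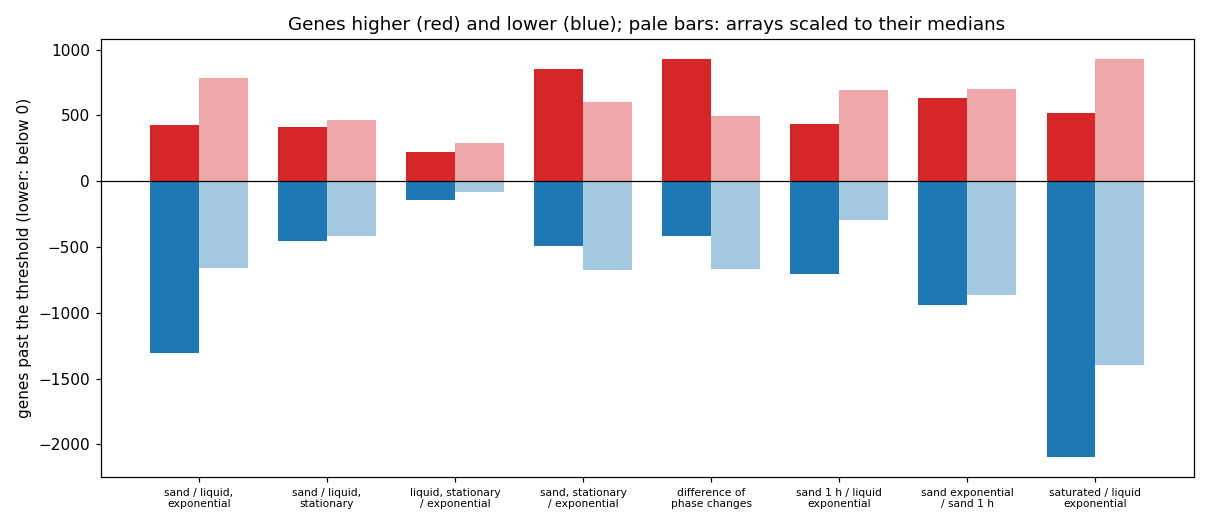
Genes past the threshold in each of the 8 comparisons (horizontal axis), higher above 0 and lower below 0 (vertical axis, number of genes), for the main scaling in full colour and for scaling to array medians in pale colour. For sand against liquid in exponential phase the main scaling has 1304 genes lower and median scaling 662.

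Scaling to array medians moved the median change of all genes by 0.40 for sand against liquid in exponential phase, 0.11 for the phases in liquid, -0.21 for the phases in sand, -0.32 for the interaction, 0.33 for sand at 1 h and 0.51 for the saturated solution. All counts of higher and lower genes are relative to the 75th percentile of the array unless another scaling is named.

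The replicates of exponential liquid were the least alike, with correlations across genes of 0.834 to 0.976, against 0.982 to 0.989 for sand at 1 h. Without replicate 2 of that group, the median change of the dibenzofuran list between exponential sand and liquid was 0.33, which passed with limma's camera at its preset correlation (p = 0.00872) and not at an estimated one (p = 0.368), against -0.15 with all arrays (adjusted p = 0.325). There 4 genes of the list rose and 4 fell, also when adjusted over the list alone. Its median was below 0 while camera placed the list above the other genes, whose median change was -0.43.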

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

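The tests of added signal, of brightness, of the slide and of the foreign probes were chosen after the values had been seen; those of harvest time, of hidden calls and of other splits were not.

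The change of phase differed between sand and liquid for 1343 genes by the interaction test. Among the named genes the difference was 7.47 log2 units for Swit_3723, 6.49 for Swit_3722, -5.39 for Swit_1412, -5.07 for Swit_3046 and -2.17 for Swit_4896. The median over the dibenzofuran list was -1.25, with an adjusted p of 0.301 at an estimated correlation. More genes passed for the phases in sand (1345) than in liquid (361). A slide difference alone would be common to both and leave about no interaction, which the 1343 genes argue against. Spread among the exponential liquid arrays enters the variance that all comparisons share, and the median SE was 0.237 for both phase changes. The count without replicate 2, 437 genes in liquid, stayed far below the sand count. It cannot test whether the spread hides calls in liquid alone, since a shared variance affects both counts. A different response to the end of growth in sand stays open, as does the choice of harvest, set by optical density in liquid and by hours in sand. Other splits do not exclude chance for this count. Of 100 splits of the 12 arrays, 6 gave at least 1343 genes, with the real one counted in both numbers. The highest count of another split was 2166. Such splits mix the large sand and phase differences into the interaction by construction, so high counts are expected from them and they are no clean test of it.

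Some of the 7 probes for genes foreign to RW1, outside the comparisons above, were brighter in sand than in liquid. In exponential phase the change was 3.60 log2 units for GFP_1, 1.66 for GFP_2, 1.29 for GFP_3 and 1.00 for LuxAB_3, and in stationary phase 3.30 for GFP_1, 1.09 for LuxAB_3 and 0.72 for GFP_3. In these phases LuxAB_2 changed by 0.75 and 0.44, without a clear rise. LuxAB_1 was well above background on 0 arrays, and echerry_1 on at most 2 of the 3 arrays of these groups, so they show neither a rise nor its absence. GFP_2 was well above background on 1 of the 3 arrays of the exponential and of the stationary liquid group, so its rises in exponential phase and at 1 h are not exact. At 1 h in sand against exponential liquid, echerry_1 rose by 1.49, GFP_2 by 1.61, GFP_3 by 0.79, LuxAB_2 by 1.102 and LuxAB_3 by 1.108, and GFP_1 changed by 0.99 (adjusted p = 0.0672). A GFP transcript in the sand cultures would raise all 3 GFP probes. The lowest of the changes of GFP_2 and GFP_3 was 0.23 (SE 0.597). Against the bound of 0.5 alone this would count against the explanation; it was left open through an allowance of 2 SE that was added after the values were seen. The value comes from GFP_2 in stationary phase, well above background on 0 of the 3 sand arrays, and so decides little. A general brightening of foreign probes was not decided either, with a median of 0.73 over the other 6 probes in the 2 phases, a value that includes LuxAB_1 at background. Binding of an RW1 transcript to GFP_1 was not tested, and no biological explanation other than a GFP transcript was tested.

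Replicate 2 of exponential liquid stood apart from replicates 1 and 3. A brightness factor for the whole array is removed by the scaling before the arrays are compared, so the ratio of deviations of 2.34 only restates the pattern and decides nothing about it. Signal added evenly to RW1 probes in replicates 1 and 3, such as from carried-over DNA, may contribute: their excess over replicate 2 was 0.436 log2 units larger in the dimmest than in the brightest of 4 classes of genes by level, between the bounds set for and against it. A later harvest of replicates 1 and 3 also stays open. The difference correlated with the phase change in sand across genes at r = 0.157, again between the bounds. The phase change in liquid itself correlated with that in sand at only r = 0.237, so this test decides little. Replicates 1 and 3 correlated with the stationary liquid arrays at 0.8741 to 0.9307, and replicate 2 at 0.8197 to 0.8985. With the saturated exponential arrays replicate 2 was the closer, at 0.8723 to 0.8872 against 0.682 to 0.7897. With exponential sand it stood at 0.805 to 0.813 against 0.7444 to 0.8012. With stationary sand the ranges overlapped. The median signal was 200 for replicate 2, and 449 and 429 for replicates 1 and 3. Which of these arrays are typical of exponential liquid was not tested.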

How the results depend on the processing

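The floor subtraction, the brighter genes alone (above the median level), the slide as a random block and the arrays of 1 slide were chosen after seeing the data. In the order sand against liquid in exponential and stationary phase, phases in liquid and in sand, interaction, sand at 1 h against liquid, and 16 h against 1 h, the main counts of 1733, 867, 361, 1345, 1343, 1142 and 1573 became 1046, 566, 136, 843, 883, 585 and 1047 with normexp, and 884, 516, 168, 776, 868, 622 and 953 in the brighter genes alone, where fewer genes were tested. With no fold minimum they became 3121, 1766, 1101, 2475, 2290 and 2753, the interaction staying within 1.5 times. For the phases in liquid, the deposited values gave 722, the groups alone 177, the slide as a block 7 and the floor subtraction 581; for the phases in sand the slide as a block gave 824. For sand at 1 h the arrays of 1 slide gave 590, with fewer arrays. For the saturated group (2614) quantile normalization gave 1615, the deposited values gave 1170 and the brighter genes 1092; the slide as a fixed block was not run because it cannot be separated from that group. The 350 genes shared by the sand effects became 172 with normexp, 548 with the brightest spot, 184 in the brighter genes and 926 with no fold minimum. The 103 shared by the phase effects became 33 with normexp, 244 with the deposited table, 58 with the groups alone, 4 with the slide as a block, 185 with the floor subtraction, 47 in the brighter genes and 417 with no fold minimum. Leaving out 1 replicate gave 239 (without replicate 1 of stationary liquid) to 538 genes for the phases in liquid and 71 to 153 shared by the phase effects. Except where the settings show it, the cause was not tested.

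The deposited table turned the direction of Swit_4896 (-0.18) and Swit_4897 (-0.30) for sand at 1 h. For sand against liquid in exponential phase, Swit_4902 turned to -0.15 without replicate 3 of exponential liquid. The median of the dibenzofuran list for sand against liquid in exponential phase turned to 0.334 without replicate 2 of exponential liquid, and ran from -0.515 to 0.334 over the replicates left out. The list's call for the phases in liquid was lost with fry (p = 0.0601 for a shift one way, by limma), and none of its 5 calls held with an estimated correlation on all arrays. Without replicate 2 of exponential liquid, those for the interaction and the phases in liquid held with it at 0.05, unadjusted over the comparisons. With the replicate as a block the counts in the same order were 1753, 879, 379, 1378, 1434, 1192 and 1588, with 2620 for the saturated group, and the block changed no call reported here. Dim spots may limit small changes, which was not tested: 86.6% of spots were well above background on the dimmest array.

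With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; in each of these 7 comparisons 1 of the 10 splits, the real one, gave as many genes. The highest count of another split was 74 against 361 for the phases in liquid, 4 against 1142 for sand at 1 h, and 0 against 1733, 867, 1345, 1573 and 2614 for the others. Of 100 splits, 1 (the real one) shared as many genes for the sand effects (350, highest other 0) and 1 for the phase effects (103, highest other 1). Mixed splits call almost no genes and so share about 0 whatever the overlap, which leaves chance overlap undecided by them.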

Other observations

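Genes with consecutive locus numbers moved together. Between 1 h and 16 h in sand the longest run of rising genes held 27 members and the longest falling run 19, and 25.9% of the genes past the threshold lay in runs of 3 or more, against at most 9.52% in 200 shuffles of the calls over the genes. For the phases in liquid the share was 38.6%, against at most 2.56%. The changes of neighbouring genes correlated across genes at r = 0.625 for the phases in liquid and 0.17 for sand against liquid in exponential phase. Neighbours are not independent replicates, and the files used here do not say which form an operon.

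Swit_5364 stood at -1.20 ± 1.04 in exponential liquid and 4.52 ± 0.47 in stationary liquid (SD, n = 3 each). In sand it stood at 5.75 ± 0.12 after 1 h, -2.54 ± 0.19 after 16 h and -1.20 ± 0.58 after 40 h. Swit_1152 stood at 3.44 ± 0.17 after 1 h in sand and 2.47 ± 0.34 after 40 h, and at -2.26 ± 0.11 after 16 h.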
